A study of Blattella germanica with 16 samples.

How the data were processed

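Fat body, the insect tissue that combines functions of vertebrate liver and adipose tissue, was taken from adult females of the German cockroach Blattella germanica. Per the labels, each female received 2 injections of 2 µg of double-stranded RNA, 7 days apart, which triggers RNA interference against the matching transcript. The dsRNA was directed against 1 of 3 insulin receptors (dsInR1, dsInR2 and dsInR3) or was a control (dsMock). The series design places the first injection on day 1 of ootheca transport, removal of the ootheca on day 12 and dissection on day 5 of the second reproductive cycle, whereas the treatment protocol places the injections 12 and 5 days before extraction, and the sources used here do not settle which holds. Animals were kept at 30 °C and 70% humidity on dog food. RNA was extracted with a GenElute total RNA kit and libraries were made by polyA selection with a TruSeq Stranded mRNA kit, per the labels' protocols. Each group had 4 libraries.

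The values used were read counts per gene, whole numbers that were not normalized, as deposited by the authors in 1 table of 28676 genes and 16 libraries. FastQC, Trimmomatic, HISAT2 and StringTie are named in the submitters' processing notes, without versions or settings, and the genome build is Bger_1.1. Whether counting used the strand of the reads, and how reads that match several genes were assigned, is not given in the sources used here. Members of gene families with similar sequences, and genes that overlap or face each other, therefore carry an uncertainty in how reads were divided, which applies here to the Cr-PI allergens, glutathione S-transferases, cytochromes P450, lipopolysaccharide-binding proteins and the genes annotated as follicle-stimulating hormone receptors. A further 32 columns of per-library values in the same table were not used here.

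The columns name the group and a library number (2, 5, 6 and 7 for dsInR1; 1, 4, 7 and 8 for dsInR2; 3, 5, 6 and 7 for dsInR3; 1, 3, 4 and 5 for the control). These are not the replicate numbers of the sample titles, so columns were assigned to groups only, and libraries are named by group and column number. The control columns carry the name of a polyhedrin dsRNA and were taken as dsMock because it is the only group left on both sides. Libraries were treated as replicates because the labels list them as separate samples; the number of animals behind each is not given in the sources used here, so p-values measure the spread between these samples. All 28676 genes matched a locus tag in a reference annotation of the same build, which lists 28774 genes and supplied the contig coordinates. The table carries a symbol for 6346 genes, and 21971 genes are annotated as hypothetical proteins. Names of products are those of the annotation and were not checked by sequence.

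Changed genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM normalization, the filterByExpr filter (10536 genes kept, 4529 of them with an informative name) and 1 coefficient per group over all 16 libraries. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05; adjusted p-values are from this test unless another tool is named. Levels are CPM (read counts scaled to a common library total) after TMM scaling, as mean ± SD of 4 libraries. Log2 fold changes are the fitted values with their standard error (SE). A gene with 0 reads in a group has no ratio; a bound was computed against a floor of 3 counts over the group. Reads amplified by PCR without molecular identifiers are not independent molecules, so such floors cover counting error only. Comparisons were each receptor treatment against dsMock, each pair of receptor treatments, the mean of the 3 receptor treatments against dsMock, and an F test over the 4 groups. The annotated insulin receptor was also tested by an exact two-sided permutation of the 4 against 4 log2 CPM values.

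Gene lists were fixed as patterns of product names: insulin receptors; insulin and TOR signalling; yolk protein precursors; hemolymph and storage proteins; the juvenile hormone pathway; the ecdysteroid pathway and nuclear receptors; lipid synthesis; lipid breakdown; carbohydrate metabolism; cytosolic ribosomal proteins; ribosome biogenesis and translation factors; the secretory pathway of the endoplasmic reticulum; detoxification enzymes; immune defence; autophagy and lysosome; RNA interference machinery; DNA replication and cell cycle; oxidative phosphorylation; nitrogen, urate and amino acid metabolism; heat shock and oxidative stress. Markers of muscle, hemocytes, ovary and germline, gut and Malpighian tubule, epidermis and trachea, and nervous tissue formed 6 further lists. The lists were tested with the camera function of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01, adjusted over the 69 combinations of a comparison and a list with at least 3 tested members. None of the calls held when the correlation was estimated from the data. The yolk list (1 gene in the table) and the juvenile hormone list (2 genes) had no member past the filter, and the insulin receptor list had 1 member.

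Genes named in the text were chosen by a rule: annotated insulin receptors and vitellogenins; for each receptor treatment, the 8 named genes with the largest rise and the 8 with the largest fall past the threshold, with at least 2 CPM in 1 of the groups and no overlap between the 4 treated and 4 control libraries; up to 4 members of each list with the smallest p; up to 2 abundant members of a list that did not pass; and the 10 smallest p where fewer than 10 genes passed. No gene in the table is annotated as a vitellogenin. Genes outside this rule are marked as chosen after their values were seen. The groups, tests, lists, naming rule and first set of alternatives were chosen before the data were examined.

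Alternatives were median-of-ratios scaling, no filter, DESeq2 1.42.0, limma-voom, fits with only the compared groups, a minimum change of 2-fold, an estimated list correlation, the fry test of limma, a separate pair of dsMock libraries for each treatment in overlaps, and leaving out each library. Alternatives chosen after the data were examined were a block on the column numbers, removal of the 10 most abundant genes, lists trimmed of members whose product does not match the theme, and list tests without each library. Overlaps between comparisons were set against 100 simulations of unchanged groups that shared the control libraries. The procedure was tested on simulated counts with 10036 genes: edgeR called 37.3%, 29.9% and 25.4% of genes changed 2-fold and 86.4%, 66.7% and 72.7% of genes changed 4-fold in dsInR1, dsInR2 and dsInR3 against dsMock. The changed genes were drawn anew for each treatment, 66 or 67 per fold, so these shares do not rank the treatments. They were also far fewer than the 3402 genes called in dsInR2, which makes the adjustment stricter than in those data. The list test called a raised list of 40 genes and 0 of 20 unchanged lists. Those lists were random draws of genes, so the run does not show how the test treats lists whose members move together. Libraries had 15.3 to 23.7 M reads, of which 5.01 to 11.6 M lay outside the 10 most abundant genes. The spread between replicates exceeded counting error by a chi-square per degree of freedom of at least 23.5, a mean over genes in which abundant genes can weigh most.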

Results

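RNA sequencing measured the fat body transcriptome of Blattella germanica females injected with dsRNA against 1 of 3 insulin receptors or with a control dsRNA. The comparisons ask what the dsRNA against each receptor changes and how far the 3 responses differ. No group received dsRNA against more than 1 receptor, so whether 1 receptor can stand in for another was not tested. Each group had 4 libraries. Total counts were 15.3 to 21.2 M reads for dsMock, 16.5 to 21.6 M for dsInR1, 16.4 to 23.7 M for dsInR2 and 15.5 to 20.99 M for dsInR3. Genes with at least 10 reads numbered 9686 ± 329 in dsMock, 9558 ± 353 in dsInR1, 10254 ± 339 in dsInR2 and 9822 ± 490 in dsInR3 (SD, n = 4). Log2 CPM of replicates correlated with r = 0.914 to 0.953 across genes, which are not independent replicates. Between replicates, the chi-square per degree of freedom against counting error was at least 23.5. It is a mean over genes in which abundant genes can weigh most, so it does not describe a typical gene.

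A single gene, C0J52_15443, was the most abundant in dsMock. It is annotated as a hypothetical protein on contig PYGN01001172.1 from 18821 to 36073, and it was chosen after its values were seen, as were the other abundant genes outside the gene lists. Its share was 55.1 ± 3.58% in dsMock, 58.2 ± 2.91% in dsInR1 and 50.1 ± 10.1% in dsInR3, where library 3 had 35.1% (SD, n = 4). In dsInR2 it was 3.36 ± 3.84%. The 4 dsInR2 libraries differed, with 6.99% in library 4, 6.38% in library 7, 0.0822% in library 1 and 2.3e-04%, or 42 reads, in library 8. On the first principal component, which held 30.0% of the variance, dsInR2 lay at 69.7 ± 10.6, dsMock at -30.3 ± 3.24, dsInR1 at -28.6 ± 9.55 and dsInR3 at -10.8 ± 17.1, with dsInR3 library 3 at 13.8.

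**Figure D1:**
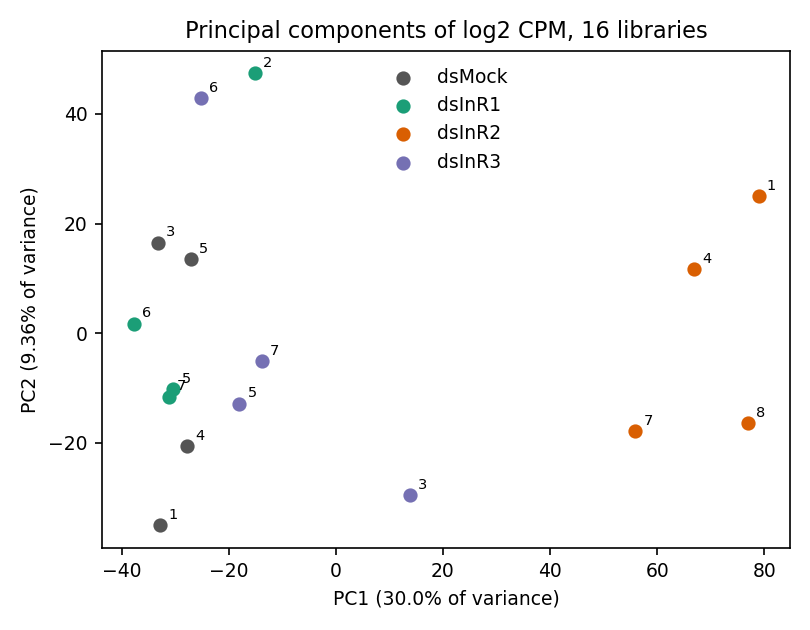
Principal components of log2 CPM of the tested genes, 1 point per library, labelled with its column number; the axes give the share of variance. The 4 dsInR2 libraries lie to the right of the other 12, and dsInR3 library 3 is the nearest of these at 13.8 on the first component.

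The annotation holds 1 insulin receptor, InR (C0J52_14014, insulin-like receptor, contig PYGN01000591.1 from 866355 to 953667), and does not say which of the 3 receptors it is. Its level was 52.8 ± 1.70 CPM in dsMock, with 54.6, 53.8, 51.9 and 50.9 CPM in libraries 3, 4, 5 and 1. In dsInR2 it fell to 5.90 ± 1.86 CPM, with 3.42, 5.95, 6.35 and 7.90 CPM in libraries 4, 1, 8 and 7 (log2 fold change -3.16, SE 0.20, edgeR adjusted p = 3.2e-07). This was 8.93-fold lower, and all 4 libraries lay below all 4 dsMock libraries (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). In dsInR1 the 4 libraries had 46.2, 47.2, 50.96 and 51.4 CPM in libraries 7, 2, 5 and 6, a mean of 48.9 ± 2.62 (log2 fold change -0.11, SE 0.19; exact p = 0.0857), a difference that did not pass. In dsInR3 they had 30.4, 38.2, 39.1 and 46.1 CPM in libraries 3, 7, 5 and 6, a mean of 38.5 ± 6.41 (log2 fold change -0.46, SE 0.19). That was 72.8% of dsMock by the fit, with an edgeR adjusted p of 0.265 over all genes, 0.0274 adjusted over the list alone, which holds this 1 gene, 0.0412 adjusted over its 3 comparisons and an exact permutation p of 0.0286. Directly compared, InR was higher in dsInR1 than in dsInR2 (log2 fold change 3.05, adjusted p = 4.0e-07) and lower in dsInR2 than in dsInR3 (-2.70, adjusted p = 1.2e-06), while dsInR1 and dsInR3 differed by 0.35 (adjusted p = 0.599). The annotation names none of the 3 targets, so depletion could not be checked target by target in any group.

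**Figure D2:**
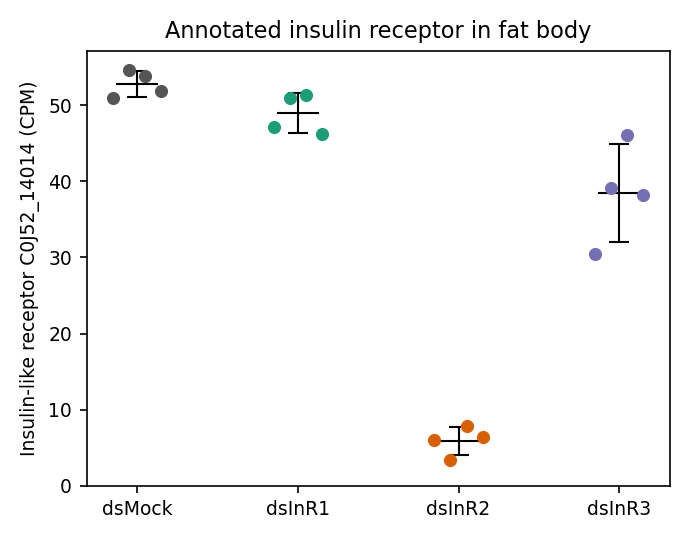
Level of the annotated insulin-like receptor C0J52_14014 in CPM by group, 1 point per library, with bars at the mean and whiskers of 1 SD (n = 4). The dsInR2 libraries lie between 3.42 and 7.90 CPM and the dsMock libraries between 50.9 and 54.6 CPM.

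With dsInR1, edgeR called no gene of the fat body transcriptome at the threshold. Genes of the secretory pathway of the endoplasmic reticulum, which folds and exports hemolymph proteins, passed the list test upward with a median log2 fold change of 0.19 over 51 members, though none passed singly and the list had adjusted p = 0.882 with an estimated correlation. Among abundant or metabolic genes that did not pass, C0J52_00889, apolipophorin (APLP), the lipid carrier of the hemolymph, had a log2 fold change of -0.02 (SE 0.25), the iron carrier transferrin (TRF) -0.70 (SE 0.86; -1.88 to -0.25 without 1 library), ATP-citrate synthase (ACLY), which makes cytosolic acetyl-CoA, -0.13 (SE 0.56), and catalase (C0J52_01914), which breaks down hydrogen peroxide, 0.11 (SE 0.53). Methyl farnesoate epoxidase (CYP15A1_3), an enzyme of juvenile hormone synthesis, had 0.35 (SE 0.65).

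edgeR called 0 genes for dsInR1 against dsMock, with 347 genes (3.29%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.197. DESeq2 called 7 genes and limma-voom called 0. The smallest p belonged to the hypothetical protein C0J52_22373, at 116 ± 56.7 CPM in dsMock and 477 ± 73.8 CPM in dsInR1 (log2 fold change 2.04, SE 0.33). The octopamine receptor OAR_1 had a log2 fold change of -2.36 (SE 0.48, adjusted p = 0.676), the hypothetical protein C0J52_05510 had 0.86 (SE 0.18, adjusted p = 0.676) and Rab3-GEF, annotated as MAP kinase-activating death domain protein, had 0.61 (SE 0.13, adjusted p = 0.736). Among the other small p-values, UNC93-like protein C0J52_17099 had -1.20, DDX42, an RNA helicase, 0.49, and the hypothetical proteins C0J52_13643, C0J52_13173 and C0J52_10604 had -0.91, 1.24 and 1.44. For cpsf4 (C0J52_10996), a subunit of the mRNA 3' end cleavage complex, the dsInR1 libraries had 0 reads and the dsMock libraries 0 to 22 (edgeR adjusted p = 0.977). By counting error alone, the level was at least 14.7-fold lower than the dsMock mean of 0.676 ± 0.546 CPM. As the lowest dsMock library also had 0 reads, this does not bound the difference between the groups. The DESeq2 calls included C0J52_22373, C0J52_05510 and cpsf4.

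None of the list members passed singly in dsInR1, over all genes or adjusted over the list alone, by edgeR. The secretory list passed camera upward (adjusted p = 2.8e-06), but it had adjusted p = 0.882 with an estimated correlation and 0.135 without dsInR1 library 6. The fry test, which asks whether the members move on balance rather than more than other genes, gave 0.470. Its member SSR3, a subunit of the translocon-associated complex, had a log2 fold change of 0.15 (SE 0.16). The other lists did not pass: the smallest adjusted p among them was 0.151, for insulin and TOR signalling with a median of -0.08. Medians of the marker lists of other cells ran from -0.26 for hemocytes to 0.18 for gut and Malpighian tubule.

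With dsInR2, many genes of the fat body differed from the control. ACLY, ACAC and Fasn, enzymes of fatty acid synthesis, rose, although the lipid synthesis list did not pass (adjusted p = 0.612), and 17 of 36 genes of lipid breakdown fell. The lists of carbohydrate metabolism and oxidative phosphorylation passed upward, with adjusted p = 0.750 and 0.882 with an estimated correlation. C0J52_01914, catalase, the peroxide-degrading enzyme, fell from 9767 ± 1375 to 10.5 ± 9.70 CPM (log2 fold change -9.86, SE 0.78, adjusted p = 1.7e-06). The hypothetical protein C0J52_15443, the most abundant transcript of the control, fell by 4.57 on the log2 scale (SE 1.55, adjusted p = 0.034). Of 5 tested genes annotated as the allergen Cr-PI, 4 rose.

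Of 10536 genes, 1851 rose and 1551 fell in dsInR2 against dsMock, 32.3% of those tested; 4473 had an unadjusted p under 0.05. A change of 2-fold or more was seen in 1014 genes that rose and 716 that fell. The call on C0J52_15443 did not hold without a filter (adjusted p = 0.062), nor without dsInR2 library 1 (0.059), dsInR2 library 4 (0.0543), dsMock library 3 (0.0546), dsMock library 4 (0.0515) or dsMock library 5 (0.0565). Without dsInR2 library 7 its log2 fold change was -5.25.

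Among abundant transcripts, neighbouring Cr-PI genes on contig PYGN01001206.1 rose. CRPI_3 (C0J52_20295, from 448103 to 476102) went from 1.49 ± 0.219% to 13.9 ± 1.29% of reads (log2 fold change 2.69, SE 0.32, adjusted p = 3.5e-05). CRPI_2 (C0J52_20293, from 426997 to 440764) went from 0.343 ± 0.0951% to 10.5 ± 2.88% (4.43, SE 0.50, adjusted p = 2.0e-05), and CRPI_4 (C0J52_20296, from 476334 to 477512) from 0.409 ± 0.0794% to 3.59 ± 0.315% (2.61, SE 0.33, adjusted p = 5.3e-05). Division of reads among these neighbours is uncertain. The fall of C0J52_15443 by itself raises the shares of other genes, whereas the log2 fold changes are after TMM scaling. The hypothetical protein C0J52_05895 (PYGN01000052.1, from 2268758 to 2348953) fell from 1.60 ± 0.185% to 0.0847 ± 0.0702% (-4.80, SE 0.58, adjusted p = 3.5e-05). Apolipophorin (C0J52_00889, PYGN01000418.1 from 852062 to 914892) rose from 2.63 ± 0.505% to 8.91 ± 1.90% of reads (1.18, SE 0.26, adjusted p = 0.0026) and transferrin (C0J52_08590, PYGN01000216.1 from 946447 to 1015015) from 0.0494 ± 0.0256% to 2.16 ± 2.01% (4.86, SE 1.01, adjusted p = 0.0019). Hexamerin (HEXA, C0J52_01002), a storage protein, fell from 225 ± 69.3 to 44.4 ± 51.4 CPM (-2.34, SE 0.74, adjusted p = 0.025), a call lost without dsInR2 library 1 (0.0681), dsInR2 library 4 (0.0608) or dsMock library 1 (0.0521); without dsInR2 library 7 its log2 fold change was -3.50. Of the 9 tested members of the hemolymph and storage protein list, 3 rose and 3 fell, and 6 rose and 3 fell adjusted over the list alone. These counts leave out the Cr-PI genes that rose. The list did not pass camera (adjusted p = 0.657). Its remaining movers are not hemolymph proteins: Pdk_0 (-1.13, adjusted p = 0.0015) and Pdk_1, kinases that switch off pyruvate dehydrogenase, fell, and the phosphatase that switches it on rose.

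**Figure D3:**
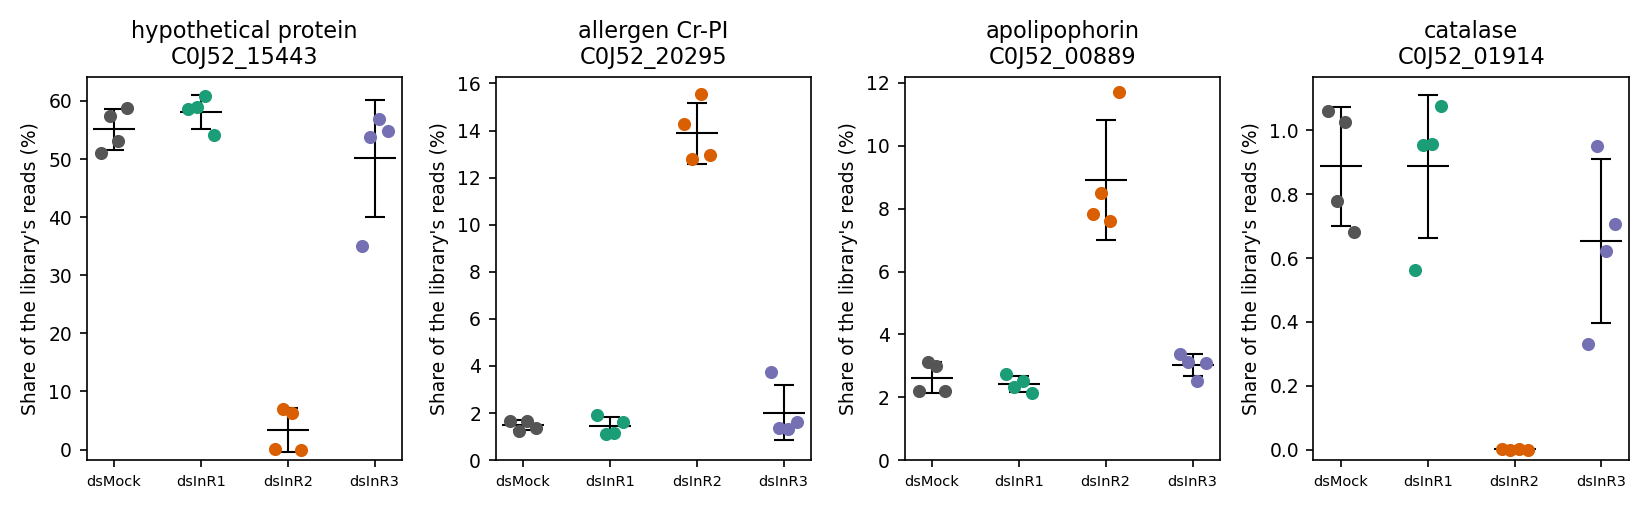
Share of each library's reads held by 4 abundant genes, in percent, 1 point per library by group, with bars at the mean and whiskers of 1 SD (n = 4); each panel has its own axis. The hypothetical protein C0J52_15443 and catalase are low in dsInR2, at 3.36 ± 3.84% and 0.00129 ± 0.00107%, and CRPI_3 and apolipophorin are high. Shares within a library depend on one another, so the fall of C0J52_15443 by itself raises the other shares.

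Of the enzymes of fatty acid synthesis, ATP-citrate synthase (ACLY, C0J52_24015, PYGN01001930.1 from 37560 to 96426) rose from 40.6 ± 8.08 to 1153 ± 1234 CPM (log2 fold change 4.83, SE 0.65, adjusted p = 7.9e-05). Acetyl-CoA carboxylase (ACAC), which makes malonyl-CoA, rose from 171 ± 40.8 to 2221 ± 1479 CPM (3.70, SE 0.54, adjusted p = 1.5e-04) and fatty acid synthase (Fasn) from 499 ± 208 to 4001 ± 3128 CPM (SE 0.54 on the log2 scale, adjusted p = 7.0e-04). Without dsInR2 library 1 the log2 values were 3.80 for ACLY and 2.36 for Fasn. Of the members that fell, ACO11_4, an acyl-CoA Delta(11) desaturase, had 0 reads in dsInR2 and 0 to 21 in the dsMock libraries. That is at least 20.5-fold lower than its dsMock mean of 0.611 CPM (adjusted p = 0.0015). A more abundant gene of the same product name, C0J52_17825, chosen after its values were seen, had 1.86 (SE 0.72, adjusted p = 0.060) and did not pass. Of the 27 lipid synthesis genes tested, 6 rose and 3 fell, also adjusted over the list alone, with a median of 0.16; the list did not pass camera (adjusted p = 0.612).

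Genes of lipid breakdown fell more often than they rose. Of 36 genes, 2 rose and 17 fell (4 and 17 adjusted over the list alone), with a median log2 fold change of -0.46. The list passed camera downward (adjusted p = 0.0010), with adjusted p = 0.750 with an estimated correlation. Hadh (C0J52_21156), hydroxyacyl-coenzyme A dehydrogenase, an enzyme of beta-oxidation, fell from 15.7 ± 2.48 to 1.15 ± 0.376 CPM (-3.76, SE 0.25, adjusted p = 4.0e-07). The thiolase ACAA2, which performs the last step of the same cycle, fell by 2.82 (SE 0.29) and the putative medium-chain acyl-CoA dehydrogenase C0J52_09993 by 2.48 (SE 0.25). HADHA, the trifunctional enzyme alpha subunit, had 0.23 (SE 0.12, adjusted p = 0.147) and did not pass. The fallen members include 2 that do not degrade fatty acids by beta-oxidation, an enoyl-CoA reductase of very-long-chain elongation and 2-hydroxyacyl-CoA lyase.

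Genes of carbohydrate metabolism rose more often than they fell, with 21 of 41 higher and 3 lower (21 and 4 adjusted over the list alone) and a median of 0.83. The list passed camera (adjusted p = 0.0043), with adjusted p = 0.750 with an estimated correlation. Glucose-6-phosphate isomerase (Pgi) rose by 1.77 on the log2 scale (SE 0.14, adjusted p = 1.7e-06), enolase (ENO_1) by 2.31 (SE 0.26), phosphoglycerate kinase (Pgk) by 2.20 (SE 0.25) and glycogen phosphorylase (GlyP), which releases glucose units from glycogen, by 1.77 (SE 0.21). Other genes of this metabolism, chosen after their values were seen, went both ways: glucose-6-phosphate dehydrogenase (ZW), the entry to the pentose phosphate pathway, rose by 3.10 (SE 0.45, adjusted p = 1.3e-04), while Pepck, the enzyme that commits oxaloacetate to gluconeogenesis, fell from 873 ± 719 to 80.7 ± 38.2 CPM (-3.44, SE 0.71, adjusted p = 0.0018; -2.77 without dsMock library 1). Members annotated as mitochondrial enolase superfamily proteins, which are not glycolytic enolases, also rose.

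Oxidative phosphorylation was the list with the highest share of risen members. Of 47 genes, 34 rose and the other 13 did not pass (37 rose adjusted over the list alone), with a median of 0.71 and a camera adjusted p of 3.7e-10, against adjusted p = 0.882 with an estimated correlation. The flavoprotein of succinate dehydrogenase (sdha) rose from 41.1 ± 6.14 to 174 ± 30.7 CPM (2.08, SE 0.20, adjusted p = 6.7e-06), the complex I subunit NDUFA12 rose by 1.14 (SE 0.15) and the ATP synthase lipid-binding protein AT5G by 1.19 (SE 0.19). A translational activator of cytochrome c oxidase I, which acts on synthesis rather than in the chain, was among the risen members.

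More genes of the protein export machinery fell than rose. Of 51 genes of the secretory pathway of the endoplasmic reticulum, 2 rose and 24 fell (3 and 25 adjusted over the list alone), with a median of -0.47; camera gave an adjusted p of 1.6e-04, and the adjusted p = 0.882 with an estimated correlation. SSR3 fell from 236 ± 43.5 to 100 ± 11.2 CPM (-1.24, SE 0.16, adjusted p = 7.4e-05), the coatomer subunit ARCN1 by 0.90 (SE 0.12) and the translocon subunit SEC61B by 1.22 (SE 0.19).

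In the translation machinery more genes rose than fell, though most did not pass. Of 75 cytosolic ribosomal protein genes, 13 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.30 and a camera adjusted p of 0.0040; it had adjusted p = 0.882 with an estimated correlation and 0.394 with fry. That call was lost without dsInR2 library 1 (0.0566), dsMock library 1 (0.0688) or dsMock library 3 (0.0574). Rpl27 rose by 0.77 (SE 0.20, adjusted p = 0.0075), whereas RPL4 fell from 579 ± 55.3 to 210 ± 127 CPM (-1.47, SE 0.33, adjusted p = 0.0031). Of 62 ribosome biogenesis and translation factor genes, 19 rose and 4 fell (27 and 4 adjusted over the list alone), with a median of 0.37 and an adjusted p of 0.0095, against adjusted p = 0.882 with an estimated correlation. NOP58, which guides RNA modification in the nucleolus, rose by 2.30 (SE 0.34) and the ribosome biogenesis protein BRX1 (C0J52_16219) by 1.60 (SE 0.20). Elongation factor 2 (EF2) had 3077 ± 241 CPM in dsMock and 3083 ± 534 CPM in dsInR2 (adjusted p = 0.993).

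The insulin and TOR signalling list did not pass (adjusted p = 0.248), with 3 of 24 genes higher and 6 lower, also adjusted over the list alone, and a median of -0.17. IGFBP, an insulin-like growth factor-binding related protein, fell from 620 ± 43.6 to 244 ± 72.6 CPM (-1.34, SE 0.23, adjusted p = 4.4e-04). The gene foxo_1 (C0J52_24290), a forkhead factor held in check by insulin signalling, fell by 0.59 (SE 0.15, adjusted p = 0.0062), and Rps6kb1_0, the S6 kinase downstream of TOR, rose by 0.62 (SE 0.15, adjusted p = 0.0051). Other movers stand apart from the pathway's core: the mRNA-binding protein IGF2BP1 rose, and RPS6KA5_1, a kinase of another S6 kinase family (-0.81, SE 0.15), the vesicle-trafficking lipid kinase pik3c3 and the translation factor mextli fell.

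Stress and detoxification genes went both ways. Of 54 heat shock and oxidative stress genes, 18 rose and 9 fell, also adjusted over the list alone (median 0.24, camera adjusted p = 0.123). The mitochondrial chaperones Hsp60 (55.1 ± 10.4 to 423 ± 155 CPM; 2.94, SE 0.34, adjusted p = 2.9e-05) and Trap1_0 (1.28, SE 0.14) rose, as did the superoxide dismutase Sod_0 (2.42, SE 0.28). Of 65 detoxification genes, 14 rose and 9 fell, also adjusted over the list alone (median 0.15, adjusted p = 0.694). The glutathione S-transferases Mgst1 (1.95, SE 0.25) and GstD1_7 (2.87, SE 0.27) rose, while CYP15A1_3 (C0J52_09986, PYGN01000349.1 from 299757 to 327450), methyl farnesoate epoxidase of juvenile hormone synthesis, fell from 2999 ± 787 to 85.6 ± 76.0 CPM (-5.13, SE 0.77, adjusted p = 1.8e-04). Of 38 autophagy and lysosome genes, 3 rose and 9 fell, also adjusted over the list alone (median -0.11, adjusted p = 0.151), with the lysosomal protease CTSB (-2.07, SE 0.22) and the autophagosome protein Atg5 (-1.23, SE 0.21) lower. Of 31 nitrogen, urate and amino acid genes, 2 rose and 7 fell, also adjusted over the list alone (median -0.26, adjusted p = 0.194); alanine aminotransferase gpt2 fell by 2.82 (SE 0.29) and ornithine aminotransferase Oat rose by 1.29 (SE 0.23).

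The next 4 lists did not pass. Among 14 immune defence genes 1 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.617; the median was 0.05 and the mean -0.08, the sign of the test), with Toll (Tl) lower by -0.89 (SE 0.21) and the recognition protein PGRP-LB_0 by -0.95 (SE 0.26), while the phenoloxidase PRP1 had 0.36 (SE 0.43) and did not pass. Among 50 DNA replication and cell cycle genes 7 rose and 4 fell, 5 and 3 adjusted over the list alone (adjusted p = 0.941; median 0.05, the sign of the test, and mean -0.10), and the risen ones include CDK11B kinases, which act in splicing and transcription. Of 6 RNA interference genes 2 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.839), and of 9 ecdysteroid and nuclear receptor genes 1 rose, also adjusted over the list alone (median -0.20, adjusted p = 0.694).

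Markers of other cells were measured beside these groups. Of 19 muscle genes 1 rose and 1 fell (median 0.24, adjusted p = 0.619); titin (sls_1) rose by 1.11 (SE 0.20), Ca-P60A, a calcium pump of many cell types, fell, and alpha-actinin (Actn) had 0.56 (SE 0.21, adjusted p = 0.054) and did not pass, except with DESeq2 (adjusted p = 0.0387) and without dsInR2 library 4 (0.0081). Of 16 gut and Malpighian tubule genes 4 rose and 2 fell (0.23, adjusted p = 0.941), with TRYP2, a trypsin, at -1.23 (SE 0.56, adjusted p = 0.109). Without 1 library TRYP2 ran from -2.15 (without dsInR2 library 8, adjusted p = 0.0044) to -0.95 (without dsInR2 library 7). Of 11 hemocyte genes 2 rose and 1 fell (0.19, adjusted p = 0.822), and of 5 ovary and germline genes 1 rose and 2 fell (median 0.05, mean -0.09, the sign of the test; adjusted p = 0.781). These counts were the same adjusted over the list alone. Of 25 nervous tissue genes 2 rose and 2 fell, with 2 rises alone left adjusted over the list alone (median -0.02, the sign of the test, mean 0.04; adjusted p = 0.788). Of 16 epidermis and trachea genes 3 rose, 2 adjusted over the list alone (median -0.07 and mean -0.01, against an upward test; adjusted p = 0.964).

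**Figure D4:**
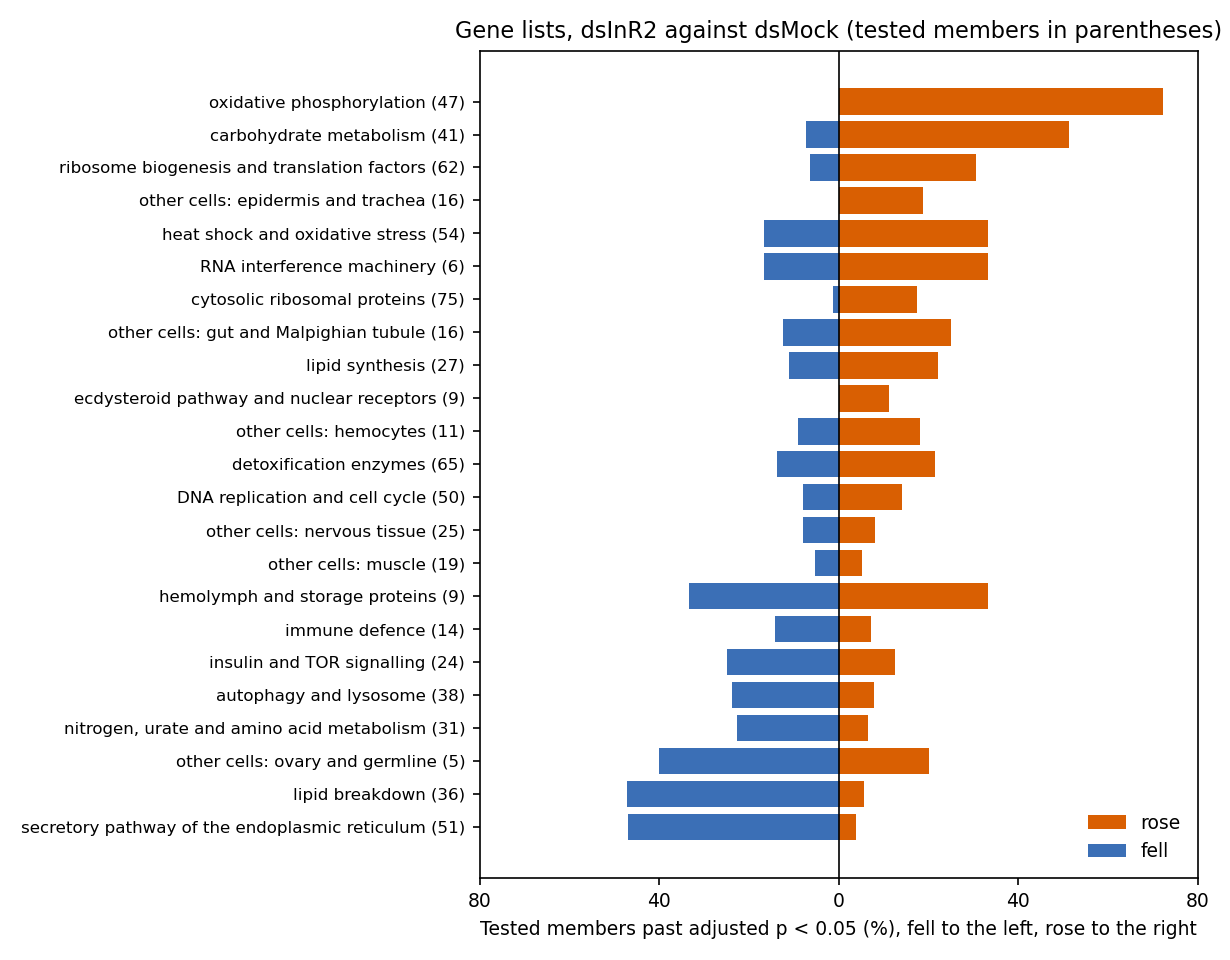
Percent of each gene list's tested members that rose (right) or fell (left) in dsInR2 against dsMock at an edgeR adjusted p under 0.05, with the number tested in parentheses. Oxidative phosphorylation has 34 of 47 members higher and the secretory pathway of the endoplasmic reticulum 24 of 51 lower.

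The largest named rises whose libraries did not overlap the controls were the lipopolysaccharide-binding proteins LPSBP_24 (log2 fold change 5.94, SE 1.28) and LPSBP_5 (5.15, SE 1.24), lectins of the hemolymph, the glutathione S-transferases GstD2_1 (5.59, SE 1.89) and GstD1_1 (5.49, SE 0.91), FSHR_1 (5.54, SE 0.996), annotated as a follicle-stimulating hormone receptor, ACLY, ZNF726, a zinc finger protein (4.70, SE 0.78), and CRPI_2. GstD2_1 lost its call (adjusted p = 0.034) without dsInR2 library 7 (0.0574) or dsMock libraries 1, 3 or 5 (0.0884, 0.0703 and 0.0634). Single libraries moved other values: 4.03 for LPSBP_24, 3.95 for LPSBP_5 and 3.89 for ZNF726 without dsInR2 library 8, 3.80 for GstD1_1 without dsInR2 library 7, 6.19 for LPSBP_5 without dsMock library 5, 6.41 for GstD2_1 without dsMock library 4 and, for FSHR_1, no ratio without dsMock library 1, the only control library with reads. The largest falls were catalase (C0J52_01914; -10.66 without dsInR2 library 7), Klk7, CYP4C1_1, a cytochrome P450 (-7.20, SE 1.15; -6.04 without dsMock library 1), FSHR_2 (-6.34, SE 0.73; -7.31 without dsInR2 library 8), the chitin-binding protein obst-E_0 (-6.21, SE 0.94; -5.61 without dsMock library 3 and -6.81 without dsInR2 library 7), the sugar transporter Slc2a1 (-6.08, SE 0.996; -6.75 without dsInR2 library 1), the progestin receptor PAQR5 (-5.46, SE 0.75) and CYP15A1_3. Klk7 (C0J52_26223), a kallikrein-like protease, had 0 reads in dsInR2 and was at least 71.4-fold lower than its dsMock mean of 2.13 ± 1.37 CPM (adjusted p = 0.013). It also had 0 CPM in each dsInR1 library but library 2 (2.41 CPM) and each dsInR3 library but library 3 (0.409 CPM).

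With dsInR3, few genes passed. Transketolase-like protein 1 (TKTL1, C0J52_15649), related to an enzyme of the pentose phosphate pathway, rose from 84.0 ± 21.4 to 241 ± 62.0 CPM (log2 fold change 1.52, SE 0.26, adjusted p = 0.031), and hexokinase type 2 (Hex-t2_1, C0J52_18479), which phosphorylates glucose, fell from 110 ± 28.8 to 46.7 ± 8.07 CPM (-1.23, SE 0.23, adjusted p = 0.041). Hex-t2_1 rose in dsInR2 (1.20, SE 0.23, adjusted p = 0.0011), and the difference between dsInR2 and dsInR3 was 2.43 (adjusted p = 1.5e-05). Genes of the secretory pathway of the endoplasmic reticulum passed the list test upward, with a median of 0.30 over 51 members, none past the threshold over all genes and adjusted p = 0.882 with an estimated correlation.

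edgeR called 21 genes higher and 11 lower in dsInR3 against dsMock, 12 and 7 of them by 2-fold or more; 1546 had an unadjusted p under 0.05. The count was 444 with DESeq2, 53 with limma-voom, 17 without a filter and 12 with only the 2 groups in the fit; the DESeq2 calls held 32 of the 32 and the limma-voom calls 31. Without 1 library it was 3, 7, 147 or 3 (dsInR3 libraries 3, 5, 6 and 7) or 0, 10, 64 or 8 (dsMock libraries 1, 3, 4 and 5), so each named call was lost in at least 1 of these.

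The other named rises were ttc37, a tetratricopeptide repeat protein (1.49, SE 0.22, adjusted p = 0.012), KTAP2, a KRTCAP2 protein (1.46, SE 0.27), psuG, a pseudouridine-5'-phosphate glycosidase (1.25, SE 0.23), the mitochondrial protease Lonp1 (1.04, SE 0.18, adjusted p = 0.033), the secernin scrn3 (1.04, SE 0.19), LPSBP_19 (0.99, SE 0.20) and Rab3-GEF (6.01 to 11.6 CPM; 0.94, SE 0.13, adjusted p = 0.012). The other named falls were the extracellular protein SPON1 (-1.16, SE 0.20, adjusted p = 0.031), Marf, which fuses mitochondria (-0.68, SE 0.13), and sn_0, an actin-bundling protein (-0.51, SE 0.10). The hypothetical protein C0J52_22373, named because it had the smallest p in dsInR1, rose to 482 ± 109 CPM (2.06, SE 0.33, adjusted p = 0.023).

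Several genes called in dsInR2 did not pass in dsInR3, with log2 fold changes as follows: ACLY 1.05 (SE 0.56), ACAC 1.08 (SE 0.49), Fasn 0.82 (SE 0.51), Hsp60 1.31 (SE 0.32, adjusted p = 0.077), CRPI_2 1.04 (SE 0.43), catalase C0J52_01914 -0.52 (SE 0.53), CYP15A1_3 0.46 (SE 0.65), TRF -0.87 (SE 0.86), APLP 0.05 (SE 0.25), IGFBP -0.69 (SE 0.22) and foxo_1 (C0J52_24290) -0.63 (SE 0.15, adjusted p = 0.067). Without dsInR3 library 3 the values were 0.76 for ACLY, 0.84 for ACAC, 0.89 for Hsp60, 0.47 for CRPI_2, -0.25 for C0J52_01914 and -0.60 for IGFBP, and over all single libraries left out TRF ran from -1.09 to -0.42 and APLP from -0.08 to 0.18. Hsp60 passed without dsInR3 library 6 (adjusted p = 0.0389), and Hsp60 and foxo_1 passed with DESeq2 (adjusted p = 0.0036 and 0.0030).

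The secretory list passed camera upward in dsInR3 (adjusted p = 7.0e-09; adjusted p = 0.882 with an estimated correlation), with no member past the threshold over all genes and 16 higher adjusted over the list alone; SSR3 had 0.28 (SE 0.16). Oxidative phosphorylation passed upward (median 0.25, adjusted p = 1.7e-05; adjusted p = 0.882 with an estimated correlation and 0.394 with fry), and so did cytosolic ribosomal proteins (median 0.14, adjusted p = 9.5e-04; adjusted p = 0.882 with an estimated correlation and 0.582 with fry), neither with a member past the threshold, also adjusted over the list alone. The ribosomal call was lost without dsInR3 library 3 (0.433) or dsMock library 3 (0.168). Heat shock and oxidative stress genes passed upward (median 0.15, adjusted p = 0.0043; adjusted p = 0.750 with an estimated correlation), with 12 higher and 2 lower adjusted over the list alone. Insulin and TOR signalling passed downward (median -0.25, adjusted p = 0.0013; adjusted p = 0.750 with an estimated correlation), with 1 higher and 5 lower adjusted over the list alone; the call was lost when members off the theme were left out (0.0583). The remaining lists did not pass, the nearest being ribosome biogenesis and translation factors (median 0.16, adjusted p = 0.0602). Carbohydrate metabolism had 1 fallen member, Hex-t2_1, and 6 higher and 3 lower adjusted over the list alone (median 0.11, the sign of the test, and mean -0.12; adjusted p = 0.323). Medians of the marker lists of other cells ran from -0.14 for hemocytes to 0.42 for gut and Malpighian tubule, the latter with an adjusted p of 0.194.

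**Figure D5:**
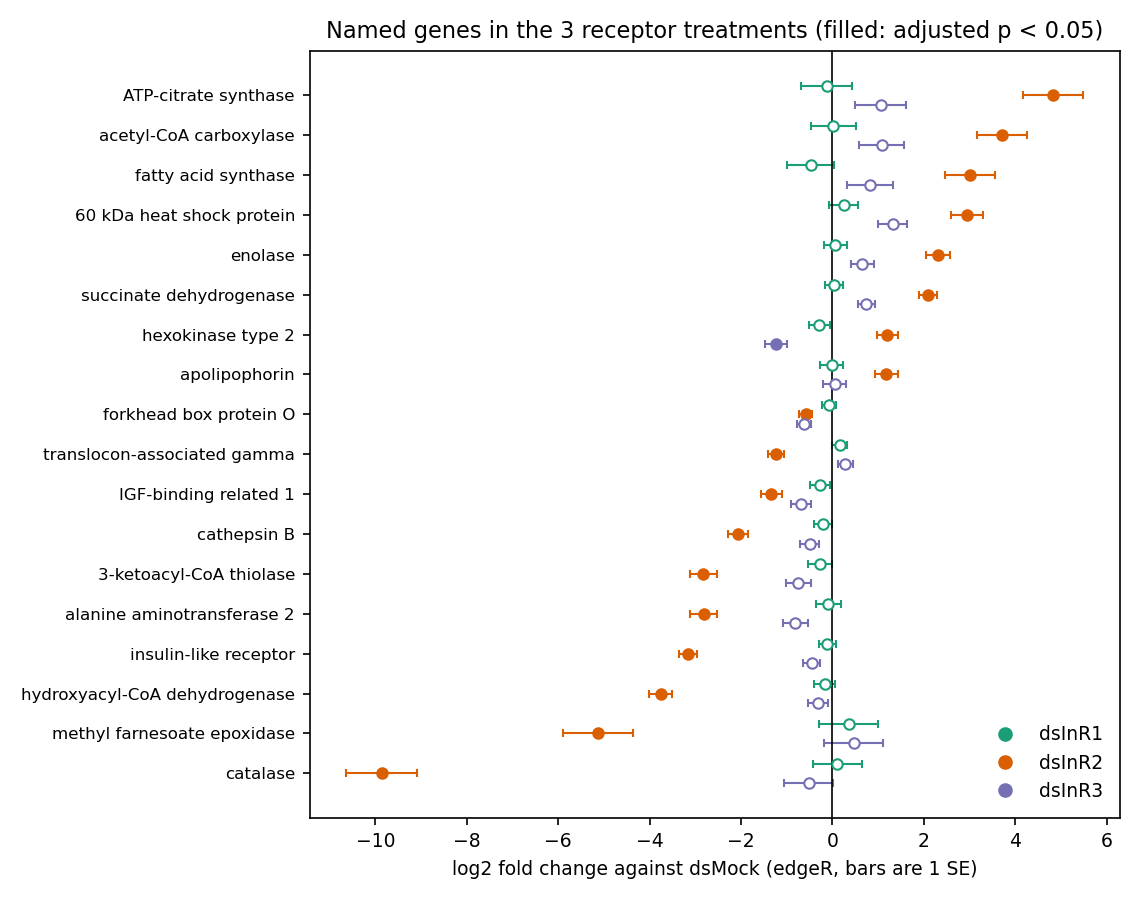
Log2 fold change against dsMock of 18 genes picked from the text after their values were seen, in the 3 receptor treatments (points, edgeR; bars are 1 SE; filled points have an adjusted p under 0.05). Hexokinase type 2 is the gene shown with filled points on both sides of 0, at 1.20 in dsInR2 and -1.23 in dsInR3.

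Set directly against each other, dsInR2 differed widely from both other receptor treatments. Catalase (C0J52_01914) was higher in dsInR1 than in dsInR2 by 9.96 on the log2 scale (SE 0.78, adjusted p = 1.6e-06) and lower in dsInR2 than in dsInR3 (-9.34, SE 0.76, adjusted p = 2.5e-06). C0J52_15443 was higher in dsInR1 than in dsInR2 (4.75, SE 1.56, adjusted p = 0.031), and its difference between dsInR2 and dsInR3 did not pass (-4.33, SE 1.54, adjusted p = 0.055). Between dsInR1 and dsInR2, edgeR called 1503 genes higher in dsInR1 and 1770 lower. Between dsInR2 and dsInR3 it called 1224 higher in dsInR2 and 1187 lower. Between dsInR1 and dsInR3 it called 0 genes, with 970 at an unadjusted p under 0.05 and a smallest adjusted p of 0.112; DESeq2 called 82, limma-voom 0, and edgeR 1 without dsInR1 library 7. The difference in Hex-t2_1 between dsInR1 and dsInR3 was 0.94 (SE 0.23, adjusted p = 0.274).

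In the mean of the 3 receptor treatments against dsMock, 398 genes were higher and 371 lower. Of these 769, 759 were called in the same direction in dsInR2, which is part of that mean. DESeq2 called 1200, and edgeR called 149, 476, 482 and 327 without dsMock libraries 1, 3, 4 and 5. The F test over the 4 groups called 3093 genes, with 4149 at an unadjusted p under 0.05.

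The 3 comparisons share their control libraries. Of the 32 genes called in dsInR3, 23 were called in the same direction in dsInR2 (17 higher and 6 lower), 2 in the opposite direction, Hex-t2_1 among them, and 7 were not called there. Independent lists of these sizes would share 3.69 and 1.62 genes, which leaves out the effect of the shared controls. Library 3 of dsInR3, which lay toward dsInR2 on the first principal component, is part of these values. Without it 3 of the 32 calls were left, as also without dsInR3 library 7. The overlap and the covariance were not computed without library 3, so its part in the likeness of dsInR2 and dsInR3 was not tested. Across genes, which are not independent replicates, log2 fold changes of dsInR2 and dsInR3 correlated with r = 0.486 (simulated 0.512) and a covariance of 0.362 (simulated 0.134, difference 0.227). With a separate pair of dsMock libraries for each treatment r was 0.157 to 0.246, the covariance 0.178 to 0.269 and the number of shared calls 0 to 38. For dsInR1 and dsInR2 r was 0.326 (simulated 0.507; separate controls 0.0468 to 0.114) and the covariance 0.224 (simulated 0.134, difference 0.0904; separate controls 0.0529 to 0.119). For dsInR1 and dsInR3 r was 0.494 (simulated 0.501; separate controls -0.0301 to 0.0859) and the covariance 0.194 (simulated 0.133, difference 0.0614; separate controls -0.0230 to 0.0627). The simulated groups carry no effects of their own, so r cannot be set against them directly. The difference in covariance was compared instead, but it also takes in any spread of the control libraries beyond the simulated spread. It is therefore not a measure of a shared response alone. The separate controls are free of this, and there the covariance of dsInR1 and dsInR3 took both signs (-0.0230 to 0.0627).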

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

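The tests of the share of dsInR2 RNA in genes that differed at least 4-fold, with single dsInR2 libraries as donors and in abundant genes, the first principal component of thinned libraries, and the removal of the 10 most abundant genes were chosen after the results were seen.

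In 23 of 416 groups of 4 libraries (5.53%), 1 library lay far from the other 3, with a gap to the nearest other that took most of the group's range (Dixon's test at its 95% critical value). Chance gives about 1 in 20 groups, or 5%, so the number of such groups is near what chance gives. The values tested were those of 98 genes and 6 measures of the libraries. Library 3 of dsInR3 had 8 of the 23.

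In dsInR3 library 3, C0J52_15443, the most abundant gene, took 35.1% of reads (others 53.8 to 56.9%) and the 10 most abundant genes 50.3% (64.0 to 65.5%). The same library had 209 CPM of heterogeneous nuclear ribonucleoprotein Q C0J52_03752 (others 82.3 to 88.5), 858 CPM of the ATP synthase lipid-binding protein C0J52_16864 (598 to 604), 10398 CPM of the Cr-PI allergen C0J52_20296 (3841 to 4522) and 8.43 CPM of the hypothetical protein C0J52_10604 (3.55 to 3.79). Near the limit of detection it had 0.900 CPM of C0J52_27160, annotated as a follicle-stimulating hormone receptor (others 0.148 to 0.205), and 0.409 CPM of the kallikrein C0J52_26223 (others 0). In the other dsInR3 libraries, titin C0J52_12784 had 36.2 CPM in library 5 (others 28.6 to 29.0), and the glutathione S-transferase C0J52_24629 had 0 CPM in library 6 (others 122.9 to 197).

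In dsInR1, library 2 had 6780 CPM of catalase C0J52_01914 (others 11231 to 12448), 195 CPM of the translocon-associated protein C0J52_17964 (283 to 286) and 2.41 CPM of the kallikrein C0J52_26223 (others 0), and library 7 had 64.0 CPM of phosphoglycerate kinase C0J52_19027 (86.2 to 88.1). In dsInR2, library 1 had 12.1 CPM of superoxide dismutase C0J52_06237 (others 7.10 to 7.19), 219.97 CPM of the succinate dehydrogenase flavoprotein C0J52_13061 (155 to 164) and 24.7 CPM of phosphoenolpyruvate carboxykinase C0J52_16143 (91.3 to 111). Library 7 had 119 CPM of the ribosomal protein C0J52_17846 (168 to 177) and library 4 had 137 CPM of the insulin-like growth factor-binding related protein C0J52_18877 (269 to 293). In dsMock, library 3 had 83.2 CPM of phenoloxidase C0J52_00852 (128 to 132), library 4 had 134 CPM of the peptidoglycan-recognition protein C0J52_07207 (89.3 to 95.02) and 4.43 CPM of the hypothetical protein C0J52_13173 (1.96 to 2.14), and library 1 had 0.299 CPM of C0J52_27160 (others 0).

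The first pattern is the number of genes changed in dsInR2 against dsMock, 3402. With the 10 most abundant genes taken out before normalization 3384 genes passed, and with each library thinned to 5.01 M reads outside those genes 3256 passed on average (3207 to 3300 in 10 draws), so the tables argue against the abundant genes or depth as the whole cause. The marker list of other cells that rose most, muscle, had a median log2 fold change of 0.24 and did not pass its test. Of its 19 genes 1 rose, titin, and 1 fell, Ca-P60A, which fat body also expresses. Of 16 gut and Malpighian tubule genes 4 rose and 2 fell, with a median of 0.23, and that list did not pass either. As lists, these medians argue against a large share of those cells, while a small share stays open. The depletion named by the design remains a candidate explanation, found and weighed on the same data.

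The second pattern is that dsInR3 library 3 lay toward dsInR2, at 13.8 on the first principal component against -25.2 to -13.8 for the others of its group. Its 19.6 M reads lay within the 15.3 to 23.7 M of the other libraries, and although its 9.73 M reads outside the 10 most abundant genes exceeded the 5.33 to 7.55 M of the other dsInR3 libraries, it stayed at 12.4 with all libraries thinned to the same number (highest other dsInR3 library -13.2, means of 10 draws), which argues against depth. A mixture with RNA of dsInR2 animals needs 1 share for all genes. The 574 genes that fell at least 2-fold in dsInR2 needed a median of 4.38% and the 964 that rose 35.7%, a difference of -31.3 percentage points (95% interval over genes -37.5 to -22.3; -37.2, -21.97, -47.2 and -28.8 with libraries 1, 4, 7 and 8 as single donors, each interval outside 0). The interval leaves out the spread between libraries: the same difference was -1.79, 24.8 and 24.6 in dsInR3 libraries 5, 6 and 7. In genes that differed at least 4-fold by share of reads it turned to 22.5 (9.79 to 30.4; -2.24 to 21.6, 9.85 to 30.7, -3.60 to 27.99 and 1.51 to 28.4 with those donors), so the test set beforehand was too narrow. Single abundant genes differed, with 5.22 to 9.78% by donor for apolipophorin (C0J52_00889), 0.354 to 19.5% for transferrin (C0J52_08590) and 56.6 to 56.8% for catalase (C0J52_01914). Over 146 abundant genes changed at least 2-fold, 1 share of 23.8 to 26.7% lay in the range given by donors and recipients for 47.7% of genes on average. With dsInR3 libraries 5, 6 and 7 in its place the best shares were 2.7%, 3.9% and 2.6%, for 52.1%, 26.0% and 57.5% of genes. Libraries with shares this low thus lay on both sides of 47.7%, so the percentage does not decide whether 1 share holds. A mixture stays open, as does a different response of the animals behind the library, which may both apply.

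The libraries were also split in other ways into groups of the same sizes. Only the real split, 1 of 35, gave as many genes for dsInR2 against dsMock (3402 called, highest other split 1) and dsInR3 against dsMock (32 called, highest other 1). The same held for dsInR1 against dsInR2 (3273, highest other 1) and dsInR2 against dsInR3 (2411, highest other 171). A share of 1 of 35 is the smallest this test can give and was not adjusted over the comparisons, so it does not exclude chance. The dsInR3 count also ran from 0 to 147 without 1 library. For the mean of the 3 treatments against dsMock, 2 of 100 drawn splits, the real one included, gave as many genes (769 called, highest other 2102). For the F test it was 1 of 100 (3093 called, highest other 2627). These draws mix all 16 libraries and so ask only whether any group differs. As 759 of the 769 genes were also called in dsInR2, they do not test an effect shared by the 3 treatments. The dsInR2 libraries differ from the other 12, but why 1 drawn split called 2102 genes, more than the 769, was not tested. For dsInR1 against dsMock and dsInR1 against dsInR3, edgeR called 0 genes, so each of the 35 splits (35 of 35) had to give as many and the count says nothing about chance. The highest other split called 1 in both, 347 and 970 genes had an unadjusted p under 0.05, DESeq2 called 7 and 82, and limma-voom 0.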

How the results depend on the processing

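The replicate block, the removal of the 10 most abundant genes, the trimmed lists and the list tests without each library were chosen after the results were seen. The cause was not tested for any change below unless stated. No named gene and no list that passed with all libraries changed direction in an alternative. Results that did not pass could: the list of cytosolic ribosomal proteins in dsInR1 passed upward with the replicate block (adjusted p = 3.3e-05; adjusted p = 0.712 with an estimated correlation) and without dsMock library 4, and downward without dsMock library 3, where no estimated correlation was run. The list of DNA replication and cell cycle turned upward and passed with the block (0.0454; adjusted p = 0.700 with an estimated correlation). PRP1 in dsInR2 ran from -0.07 to 0.65 without 1 library. The log2 fold change of the annotated insulin receptor ranged without 1 library from -0.13 to -0.08 in dsInR1, -3.33 to -2.97 in dsInR2 and -0.55 to -0.36 in dsInR3.

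A minimum change of 2-fold, which can only remove genes, left 1730 genes in dsInR2 against dsMock, 19 in dsInR3 against dsMock, 1657 between dsInR1 and dsInR2, 1140 between dsInR2 and dsInR3 and 241 for the mean of the 3 treatments. Without a filter dsInR3 had 17, with limma-voom 53 and with only the 2 groups in the fit 12. DESeq2 called 7 in dsInR1, 444 in dsInR3, 82 between dsInR1 and dsInR3 and 1200 for the mean. With median-of-ratios scaling dsInR2 had 3395 and dsInR3 39.

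Without 1 library, dsInR1 against dsMock had 0 to 0 genes, dsInR2 2892 to 3401, dsInR3 0 to 147, dsInR1 against dsInR2 2642 to 3257, dsInR1 against dsInR3 0 to 1, dsInR2 against dsInR3 1719 to 2611, the mean 149 to 859 and the F test 2666 to 3105. Fewer libraries leave fewer degrees of freedom. The lists past the threshold numbered 0 to 4 in dsInR1, 5 to 7 in dsInR2 and 4 to 7 in dsInR3.

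With an estimated correlation, lists past the threshold numbered 0 in dsInR1, 0 in dsInR2 and 0 in dsInR3, also with the block added. With fry, which tests whether members move on balance and not against other genes, they numbered 0 in dsInR1, 9 in dsInR2 (5 shared with the 6 of camera) and 3 in dsInR3. With a separate pair of dsMock libraries for each treatment, dsInR1 and dsInR2 shared 1 call with dsMock libraries 1 and 3 given to the first, and dsInR2 and dsInR3 shared 0, 0, 0, 38, 2 and 7.

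The columns do not carry the titles' replicate numbers, so no pairing by them was tested. A replicate block on the column numbers, with 5 residual degrees of freedom, gave 1 gene in dsInR3 against dsMock, 2552 in dsInR2 against dsMock, 1058 between dsInR1 and dsInR2, 816 between dsInR2 and dsInR3, 1431 for the F test and 8 lists in dsInR1. Residuals of libraries with the same number correlated with r of -0.126 to 0.153 (median 0.0170, 10 pairs), and 2 libraries correlated best with their own number.

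Of the named genes called in dsInR2, 61 of 72 passed in each alternative run for them and 11 were lost in at least 1; in dsInR3 all 13 were lost in at least 1. Of genes changed 1.5-fold in simulated counts, edgeR recovered 4.48%, 1.49% and 5.97% for dsInR1, dsInR2 and dsInR3. The changed genes were few and drawn anew for each treatment, so these shares do not rank the treatments. Depth was not varied there, and thinning left 3256 of the 3402 calls in dsInR2 on average.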

Other observations

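The tests of product words were chosen after the results were seen. Among 4529 tested genes with an informative name, 180 words carried by at least 10 genes were tested for rises and falls in dsInR2 against dsMock (360 one-sided Fisher's exact tests, 24 past an adjusted p of 0.05). Against a background of 20.2% that rose, names with pore had 7 of 10 (adjusted p = 0.0191), among them the nucleoporins Nup155_0 (log2 fold change 2.08) and Nup107 (1.57). Names with dna-directed, the RNA polymerases, had 15 of 25 (8.6e-04), with Polr1c at 1.56 and RpII215 at 0.81, and names with ribonucleoprotein 16 of 31 (0.0037), with Syncrip at 2.24. Names with lipopolysaccharide-binding had 12 of 25 (0.0278), s-transferase 8 of 13 (0.0247), dehydrogenase 53 of 124 (1.8e-06) and translocase 7 of 11 (0.0321).

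Against a background of 17.2% that fell, names with solute, the solute carriers, had 12 of 22 (adjusted p = 0.0033), with Slc2a1 at -6.08. Names with Golgi had 8 of 13 (0.0101), with Cog5 at -1.31 and sau at -1.42. Genes of 1 family share words, so these tests are not independent. Each test also takes its genes as independent, so its p-value can be too small where genes move together or share reads.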
